A study of Mus musculus with 23 samples.

How the data were processed

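Mouse bone marrow progenitors were profiled on 23 Affymetrix arrays, 1 sample per array. Per the labels' protocols, KSLs and CMPs of control or knockout donors were cultured in 100 ng/ml stem cell factor, 100 ng/ml thrombopoietin and 10 ng/ml IL-3, infected with a retrovirus carrying MLL-AF9 and GFP, and transplanted into irradiated recipients. RNA was amplified with a whole-transcriptome kit for small inputs, and biotin-labelled product was hybridised. The deposited values are log2 expression values of 34760 probe sets made with RMA, per the submitters' processing notes, whose version is not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays and summarises probes, so levels are comparable within a probe set and not between them, and changes of dim genes are compressed. Deposited log2 values were floored at exactly 3 for 2952 to 3379 probe sets per array (988 on every array) and reached 13.64. Their precision is limited by the number of arrays. Of the 253 pairs of arrays the closest had a correlation of 0.995, and at most 0.00288% of the probe sets above the floor held identical values in a pair, so each array counted as 1 sample.

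Gene symbols came from the platform annotation: 21640 probe sets had 1 symbol, 1321 several and 11799 none listed. Of the first, 21553 matched a RefSeq gene of GRCm38.p6 by Entrez identifier, which changed 0 symbols, and 87 kept the annotation's symbol. For the 954 genes with several probe sets the one with the highest mean over all arrays was used, which left 19937 genes. Probe sets with several symbols or none were kept apart and enter no gene count. Arrays were assigned to 9 groups by the labels. A linear model of group means was fitted with limma 3.58.1 in R 4.3.3 to all 23 arrays, with empirical Bayes moderation and a trend in the prior variance, and a gene counted as changed at a Benjamini-Hochberg adjusted p below 0.05. L-GMP groups and the KSL and CMP reference groups entered a contrast with equal weight per group. The comparisons were knockout against control CMPs, control GMPs against CMPs, knockout against control L-GMPs, control and knockout L-GMPs each against the MLL-AF9 knockout progenitors without leukaemia, CMPs against KSLs of the latter, secondary against primary control L-GMPs, MLL-AF9 knockout against knockout CMPs, control L-GMPs against GMPs, and the difference of the knockout effects in L-GMPs and CMPs. The difference between groups that lie in different experiments, such as transplanted and untreated marrow, cannot be told apart from a difference between array batches, since no batch or scan date was used here.

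The 18 gene lists (primary granule, secondary granule and mature neutrophil, granulocyte-monocyte receptors and regulators, monocyte and macrophage, stem cell, erythroid, megakaryocyte, mast cell with basophil and eosinophil, lymphoid progenitor, mature lymphocyte, dendritic cell, stromal, MLL-fusion target, cell cycle, interferon, cytokine response, immediate early and ribosome biogenesis) hold 271 entries, 249 of them measured, and were tested with camera at a preset correlation of 0.01 and again with an estimated one, BH-adjusted over the lists of a comparison. The groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Cebpa, the 8 largest rises and 8 largest falls among changed genes whose arrays do not overlap between the sides (leaving out predicted, clone-named, small RNA, olfactory receptor, immunoglobulin and T cell receptor segment and Y-linked genes and Xist), and up to 4 changed members of each list or, where none changed, up to 2 given as values. Where the arrays of the compared groups differed in noise, a further condition was added after seeing the data: a named gene is said to rise or fall in the L-GMP and MLL-AF9 comparisons if it passed with equal and with array weights. The median absolute residual was 0.088 in control CMPs, 0.086 in knockout CMPs, 0.0926 in GMPs, 0.197 and 0.219 in MLL-AF9 CMPs and KSLs, 0.212 and 0.133 in primary and secondary control L-GMPs and 0.11 in knockout L-GMPs.

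The code was tested on simulated data for the 19937 genes, with 200 genes changed by known amounts. With equal noise in every group, the share of genes changed 2-fold and 4-fold that was recovered was 77% and 97% for knockout against control CMPs, 78% and 98% for GMPs against CMPs, 71% and 98% for knockout against control L-GMPs, 82% and 94% for control L-GMPs against non-leukaemic progenitors, 75% and 95% for knockout L-GMPs against them, 59% and 96% for MLL-AF9 CMPs against KSLs, 55% and 96% for secondary against primary control L-GMPs, 64% and 96% for MLL-AF9 knockout against knockout CMPs and 77% and 98% for control L-GMPs against GMPs, and 2 of 2 shifted lists were called in each. With noise as observed in each group, the share of calls that were false under equal and array weights was 0.5% and 6.3% for knockout against control CMPs, 1.44% and 5.93% for GMPs against CMPs, 13% and 4.59% for knockout against control L-GMPs, 66.9% and 4.79% for control L-GMPs against non-leukaemic progenitors, 25.7% and 5.53% for knockout L-GMPs against them, 80.5% and 5.79% for MLL-AF9 CMPs against KSLs, 53.5% and 4.69% for secondary against primary control L-GMPs, 34% and 10.1% for MLL-AF9 knockout against knockout CMPs and 7.14% and 3.5% for control L-GMPs against GMPs. Each share comes from 1 simulated data set and depends on the 200 genes changed there. It is therefore not the false share of the calls reported below. The equal-weights fit, chosen before these values were known, stays the basis of the counts.

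Replicate numbers 1 and 2 of the MLL-AF9 KSLs and CMPs stand for the same mice per the labels, and deviations of arrays of the same mouse correlated (0.45 for mouse 9 and 0.26 for mouse 11). Arrays not known to share a mouse reached 0.302 (over genes outside the mast cell and MLL-fusion target lists), so the value of mouse 11 does not show a shared mouse. With 2 KSL arrays the deviations of mice 9 and 11 mirror each other, so their values are not independent. Elsewhere the labels give only a number. Alternatives tried were a fit on the compared arrays alone, quantile normalization again, subtraction of array medians, a filter on dim genes (mean above the 40th percentile, log2 4.75, in a compared group), the mean of a gene's probe sets, no variance trend, a threshold of 2-fold as well, array weights, replicate number as a block, mouse and leukaemia as a random block, leaving out each array in turn, primary or secondary recipients only, equal weight per array, the knockout leukaemia averaged to 1 sample, KSLs or CMPs as the only reference, an estimated correlation for camera, and split control or reference arrays for values that share them. Mouse 9 left out, high Xist as a covariate and a crossed numbering of the secondary recipients were added after seeing the data. Simulated unchanged groups, with the same noise in every group, gave the values with no effect for comparisons that share arrays. Plots were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Raw scanner files were not used here.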

Results

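Expression was measured on 23 Affymetrix arrays of sorted mouse bone marrow progenitors, with and without C/EBPα, the transcription factor that drives entry into the granulocyte and monocyte lineages. Cebpa had been deleted with an interferon-inducible Cre recombinase, and mice whose floxed gene was left intact served as controls. Common myeloid progenitors (CMPs) from control and knockout mice were on 4 arrays each. Granulocyte-macrophage progenitors (GMPs) from controls were on 3. These cells were taken 5 days after 3 injections of poly I:C. The other arrays came from recipients of cells transduced with the leukaemia fusion MLL-AF9. Leukaemic GMPs (L-GMPs) came from 2 primary and 2 secondary control recipients, and from 1 primary knockout leukaemia and 2 secondary recipients of it. GFP-positive stem and progenitor cells (KSLs, 2 arrays) and CMPs (3 arrays) came from knockout recipients without leukaemia. The knockout leukaemia arose after vectors expressing IL-3 and GM-CSF had been injected, and its 3 arrays stand for 1 leukaemia. No label states which control recipients shared a donor. The p-values measure the spread between these samples, and the donors behind them are mostly unstated.

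Cebpa itself was read first, as a check of the genotype in the labels. Its log2 level (mean ± SD) was 7.54 ± 0.27 (n = 4) in control CMPs, 7.53 ± 0.23 (n = 3) in control GMPs, 7.82 ± 0.19 (n = 2) in primary and 7.36 ± 0.00 (n = 2) in secondary control L-GMPs. In knockout cells it was 5.31 ± 0.27 (n = 4) in CMPs, 5.04 ± 0.25 (n = 2) in MLL-AF9 KSLs, 4.67 ± 0.16 (n = 3) in MLL-AF9 CMPs, 5.15 (n = 1) in the primary L-GMPs and 4.61 ± 0.40 (n = 2) in the secondary L-GMPs. No knockout array overlapped a control array, so no array went against the genotype in its label. Cebpa was level in control CMPs and GMPs, so it does not check cell type or mouse. Sex differed within groups: Xist, transcribed from the inactive X chromosome of females, was high on 3 of 4 control and 1 of 4 knockout CMP arrays, on 3 of 3 GMP arrays, on all 5 arrays of MLL-AF9 KSLs and CMPs, on 1 of 4 control L-GMP arrays and on 3 of 3 knockout L-GMP arrays.

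**Figure D1:**
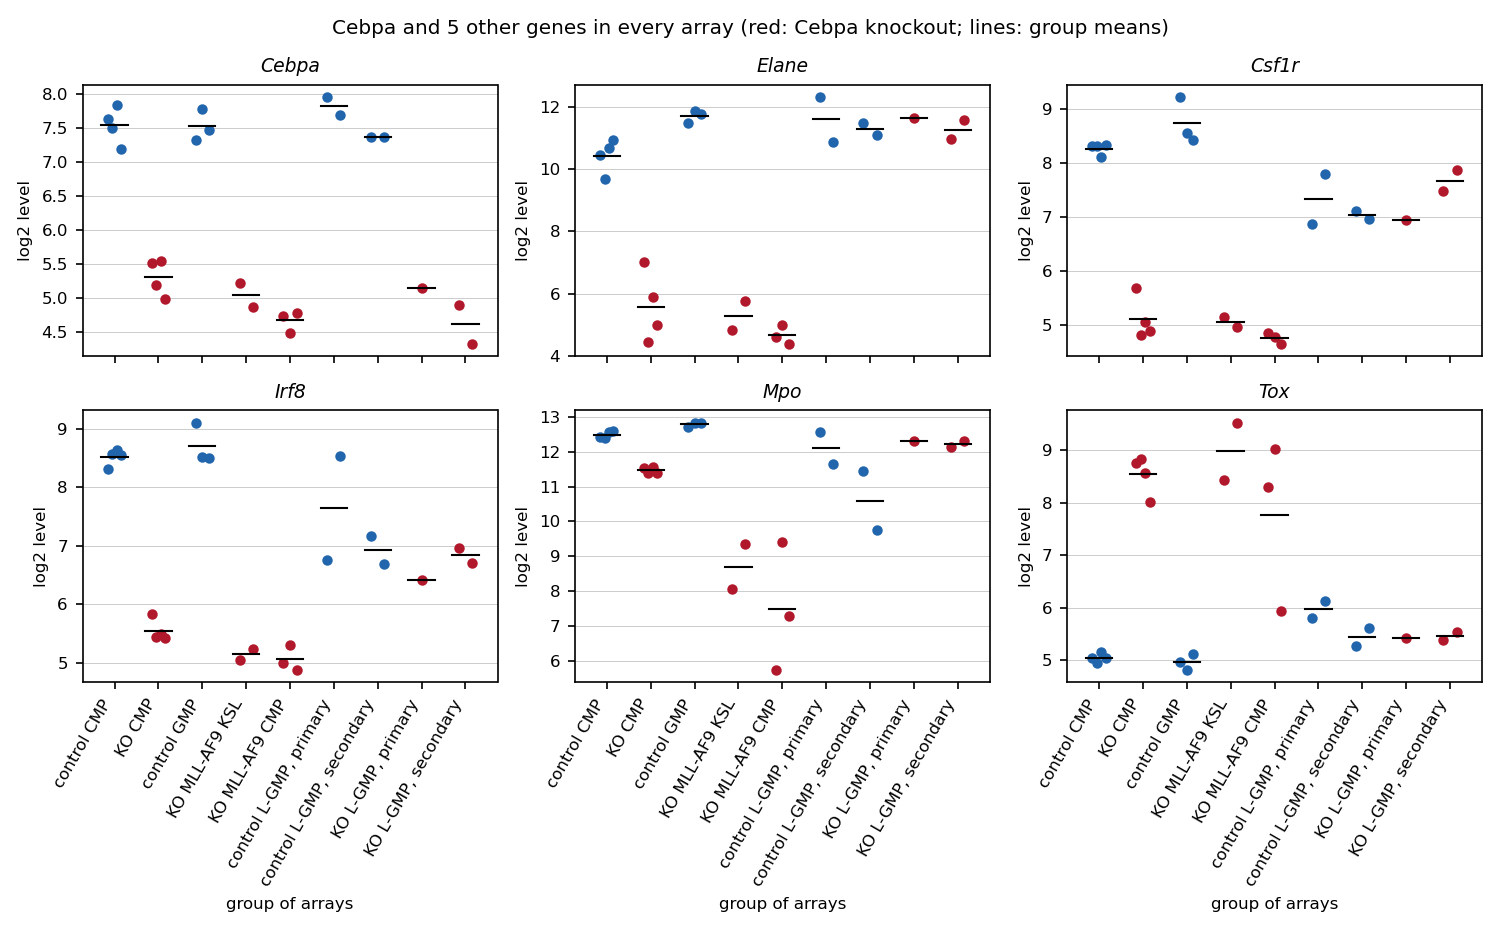
Log2 level of Cebpa, Elane, Csf1r, Irf8, Mpo and Tox on each of the 23 arrays, by group (points are arrays, lines are group means, knockout groups in red). Cebpa lay between 7.19 and 7.96 on the control arrays and between 4.33 and 5.55 on the knockout arrays.

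The first comparison asked what CMPs express without C/EBPα. Genes of the neutrophil primary granules were lower in the knockout: Elane (−4.85 ± 0.46), neutrophil elastase, stood at 5.58 ± 1.12 (SD, n = 4) in knockout and 10.43 ± 0.54 (SD, n = 4) in control CMPs, a 28.9-fold difference, and Ctsg (−3.93 ± 0.38), Prtn3 (−3.35 ± 0.39) and Ms4a3 (−3.29 ± 0.54) also fell (log2 change ± SE). Of the 9 primary granule genes 6 fell and 3 did not pass (limma, BH-adjusted, 6 adjusted over the list alone). Monocyte and macrophage genes fell with them, 9 of 12 (11 adjusted over the list alone), among them F13a1 (−4.30 ± 0.27), the A subunit of coagulation factor XIII, Ly86 (−4.05 ± 0.35), Ms4a6c (−3.65 ± 0.39) and Mpeg1 (−3.01 ± 0.30). Receptors and regulators of the granulocyte-monocyte lineage fell for 5 of 14 (8 adjusted over the list alone), including the M-CSF receptor Csf1r (−3.17 ± 0.22), the monocyte transcription factor Irf8 (−2.98 ± 0.27), Il6ra (−1.92 ± 0.19) and the G-CSF receptor Csf3r (−1.05 ± 0.15). The haptoglobin gene Hp (−4.13 ± 0.29) and Anxa3 (−3.81 ± 0.30) completed the 8 largest falls. The median changes of the 3 lists were −2.12, −2.19 and −0.85. Camera's BH-adjusted p was 1.37e-10, 3.80e-19 and 2.79e-11 for these lists, and adjusted p = 0.0107, 0.0031 and 0.0107 with an estimated correlation. Markers of other cell types moved too: Prg2, the eosinophil major basic protein, fell by 2.75 and Epx, eosinophil peroxidase, by 0.80, while the median of the megakaryocyte list was 0.42 and that of the erythroid list −0.23, neither past the threshold (adjusted p = 0.0767 and 0.809).

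Higher in knockout CMPs were Tox (3.50 ± 0.45), a lymphoid DNA-binding protein, Scin (3.29 ± 0.70), an actin-severing protein, Phlda1 (2.61 ± 0.23), Clec4e (2.29 ± 0.45), Zbtb10 (2.16 ± 0.20), Ctla2b (2.16 ± 0.39), Ctsw (1.96 ± 0.28) and Lax1 (1.90 ± 0.26), whose arrays did not overlap between the groups. Immediate early genes rose for 5 of 11 (6 adjusted over the list alone), including Egr1 (1.35 ± 0.21), Junb (1.03 ± 0.18), Ier2 (1.17 ± 0.27) and Zfp36 (0.81 ± 0.19). For the list, camera gave BH-adjusted p = 2.65e-07, and adjusted p = 0.126 with an estimated correlation. The STAT5 targets Pim1 (0.99 ± 0.27) and Pim2 (0.96 ± 0.24) rose, 2 of 14 in the cytokine response list both over all genes and adjusted over the list alone. As a list, these had camera BH-adjusted p = 0.0466, and adjusted p = 0.424 with an estimated correlation. In the cell cycle list the mitotic kinases Aurka (−0.43 ± 0.10) and Aurkb (−0.50 ± 0.13) fell, 2 of 24 (7 adjusted over the list alone). The list had a median of −0.30 and camera BH-adjusted p = 1.71e-06, with adjusted p = 0.253 with an estimated correlation. The nucleolar methyltransferase Fbl (−0.40 ± 0.10) fell, 1 of 16 ribosome biogenesis genes (2 adjusted over the list alone). Camera gave that list BH-adjusted p = 7.21e-05, and adjusted p = 0.298 with an estimated correlation. The mature neutrophil regulator Cebpe (−0.84 ± 0.20) fell, 1 of 15 secondary granule genes (3 adjusted over the list alone). Secondary granule genes had camera BH-adjusted p = 0.0451, and adjusted p = 0.427 with an estimated correlation. The mast cell, basophil and eosinophil list, 2 of 13 lower (5 adjusted over the list alone), had camera p = 0.0113, and adjusted p = 0.424 with an estimated correlation. Dendritic cell genes had 0 of 12 members past limma's threshold (H2-Aa −1.38 ± 0.42, BH-adjusted p = 0.0777). Their list had camera BH-adjusted p = 0.0466, with adjusted p = 0.424 with an estimated correlation.

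Single members of other lists passed in knockout CMPs: Jmjd1c (0.84 ± 0.14) rose and Bcl2 (−0.84 ± 0.19), an inhibitor of apoptosis, fell among 15 MLL-fusion targets. In the same way Angpt1 (1.47 ± 0.35) rose among 13 stem cell genes, Sparc (0.43 ± 0.11) rose among 12 stromal genes and Bst2 (−0.81 ± 0.19) fell among 16 interferon response genes. These lists were not called by camera (adjusted p = 0.799, 0.178, 0.608 and 0.354). The stromal list had a median of 0.03, a mean of −0.01 and an upward test. Adjusted over the list alone the same members passed, and 1 lymphocyte gene lay lower. Lymphoid progenitor genes (Flt3 −1.32 ± 0.67), mature lymphocyte genes (Cd79b −0.64 ± 0.18), erythroid genes (Rhag −1.49 ± 0.64) and megakaryocyte genes (Itga2b 0.79 ± 0.41) had 0 members past the threshold in limma. In all, 979 of 19937 genes differed in limma's BH-adjusted test, 453 higher and 526 lower without C/EBPα. At least 2-fold were 110 and 168 of these. The 4 arrays of each side did not overlap for 4215 genes (21.1%, against 2.86% by chance). The count was 576 without control CMP array 3, 587 without control CMP array 4. It was 530 without knockout CMP array 1, 563 without knockout CMP array 2, and 593 with high Xist as a covariate. Array weights called 3762 and a fit on the 8 arrays alone 3220. Some calls ended when 1 array was left out. For these, and in each comparison below, the array giving the highest BH-adjusted p is named, with the number of arrays of those left out in turn that ended the call. Without knockout CMP array 2, the BH-adjusted p was 0.0604 for Cebpe (2 of 8) and 0.0883 for the cytokine response list (5 of 8). Leaving out control CMP array 4 gave a BH-adjusted p of 0.0807 for Angpt1 (5 of 8), 0.0666 for Epx (4 of 8), 0.0992 for Sparc (7 of 8), 0.207 for the dendritic cell list (4 of 8) and 0.106 for the secondary granule list (4 of 8). With knockout CMP array 1 left out, the BH-adjusted p was 0.0656 for Bcl2 (4 of 8), 0.0748 for Aurka (5 of 8), 0.166 for Aurkb (8 of 8), 0.0822 for Bst2 (6 of 8), 0.123 for Pim2 (6 of 8), 0.168 for Pim1 (6 of 8), 0.0656 for Ier2 (5 of 8), 0.069 for Zfp36 (4 of 8) and 0.0903 for Fbl (4 of 8).

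The step from CMP to GMP in control marrow was compared to describe normal maturation. GMPs had higher levels of the calprotectin genes S100a8 (4.03 ± 0.65) and S100a9 (3.79 ± 0.71), the eosinophil granule genes Prg2 (3.25 ± 0.44), Epx (1.99 ± 0.20) and Ear6 (2.71 ± 0.13), Clec4a2 (3.64 ± 0.48), Sgms2 (3.17 ± 0.34), Olr1 (2.97 ± 0.51) and Mgl2 (2.68 ± 0.55) (log2 change ± SE, n = 3 GMP and 4 CMP arrays). Secondary granule genes rose for 4 of 15 (7 adjusted over the list alone), including Cebpe (1.59 ± 0.21) and lipocalin-2, Lcn2 (2.16 ± 0.46). Erythroid genes fell for 5 of 16 (12 adjusted over the list alone), among them the carbonic anhydrases Car1 (−3.98 ± 0.74) and Car2 (−2.99 ± 0.45) and the erythroid factors Gfi1b (−2.08 ± 0.31) and Gata1 (−1.83 ± 0.30). The remaining large falls were platelet factor 4, Pf4 (−3.73 ± 0.68), Mt2 (−3.21 ± 0.69), Ces2g (−3.20 ± 0.66), Slc14a1 (−3.17 ± 0.43), Ctla2a (−2.78 ± 0.28) and Mfsd2b (−2.64 ± 0.50). Cebpa was level between the groups (−0.01 ± 0.18).

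Of the gene lists, 5 were called in GMPs against CMPs with either correlation: erythroid (median −1.58, camera BH-adjusted p = 1.02e-19), secondary granule (0.90, p = 7.40e-12), granulocyte-monocyte receptors (0.54, p = 2.24e-08), stem cell (−0.45, p = 1.21e-05) and immediate early genes (−0.81, p = 4.07e-12). Among them 0 of 14 receptors and regulators passed over all genes in limma (Gfi1 0.79 ± 0.18, adjusted p = 0.0556) and 6 rose adjusted over the list alone. The stem cell ligand and receptor Angpt1 (−2.21 ± 0.38) and Tek (from 5.14 ± 0.26 to 4.14 ± 0.14, mean ± SD, SE of the change 0.23) fell. So did Egr1 (−2.12 ± 0.23) and Jun (−1.17 ± 0.24), and 7 immediate early genes fell adjusted over the list alone. The preset correlation alone also called primary granule genes (0 of 9 past limma's threshold, 4 adjusted over the list alone, Prss57 1.31 ± 0.43; adjusted p = 0.0611 with an estimated correlation). It further called monocyte genes (Adgre1 (1.09 ± 0.24), 3 adjusted over the list alone; adjusted p = 0.0996 with an estimated correlation) and megakaryocyte genes (Pf4, 3 adjusted over the list alone; adjusted p = 0.178 with an estimated correlation). The same held for dendritic cell genes (median −0.12, H2-Ab1 −0.88 ± 0.30), MLL-fusion targets (−0.54, Bcl2 −0.84 ± 0.21) and ribosome biogenesis genes (−0.22). Each had 0 members past limma's threshold (0, 2 lower and 0 adjusted over the list alone), and they had adjusted p = 0.113, 0.203 and 0.203 with an estimated correlation. The mast cell, basophil and eosinophil list rose for 3 of 13, Prg2, Epx and Prss34 (2.47 ± 0.46) (3 higher and 1 lower adjusted over the list alone), with a median of −0.03 and a mean of 0.37. Camera gave it BH-adjusted p = 0.0311, and adjusted p = 0.397 with an estimated correlation. The adhesion genes Vcam1 (1.80 ± 0.33) and Fn1 (2.05 ± 0.43) rose among 12 stromal genes (2 adjusted over the list alone), a list that camera did not call (BH-adjusted p = 0.212). The lymphoid progenitor, lymphocyte, cell cycle, interferon and cytokine lists had 0 members past the threshold in limma.

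In all, 209 genes differed between GMPs and CMPs (limma, BH-adjusted), 143 higher and 66 lower in GMPs, 84 and 45 of them at least 2-fold. The arrays did not overlap for 3250 genes (16.3%, against 5.71% by chance). Leaving out control CMP arrays 1, 2 and 3 in turn gave 115, 94 and 99 genes. The same for control GMP arrays 1, 2 and 3 gave 128, 70 and 96. Array weights called 1257 genes and a fit on the 7 arrays alone 643. When control GMP array 2 was dropped, the BH-adjusted p was 0.1 for S100a9 (4 of 7), 0.0727 for Olr1 (2 of 7), 0.178 for Mgl2 (5 of 7), 0.118 for Ces2g (6 of 7), 0.192 for Lcn2 (6 of 7), 0.0696 for Angpt1 (1 of 7), 0.053 for Gata1 (1 of 7), 0.086 for Vcam1 (3 of 7) and 0.0512 for the dendritic cell list (1 of 7). After removal of control GMP array 1 the BH-adjusted p was 0.0697 for Car1 (4 of 7), 0.14 for Mt2 (6 of 7), 0.0773 for Mfsd2b (5 of 7), 0.19 for Adgre1 (6 of 7), 0.127 for Jun (6 of 7) and 0.14 for the monocyte list (1 of 7). Without control GMP array 3, the BH-adjusted p was 0.0754 for Pf4 (2 of 7) and 0.238 for Tek (6 of 7). Leaving out control CMP array 2 gave a BH-adjusted p of 0.0585 for Prss34 (3 of 7) and 0.0717 for the mast cell list (3 of 7). With control CMP array 3 left out, the BH-adjusted p was 0.102 for Fn1 (4 of 7). S100a8, Prg2, Epx, Ear6, Clec4a2, Sgms2, Cebpe, Car2, Gfi1b, Slc14a1, Ctla2a and Egr1 passed without any 1 array.

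The loss of C/EBPα in CMPs and the passage from CMP to GMP ran in opposite directions across genes. Over 19937 genes, which are not independent replicates, the log2 changes had Pearson r = −0.373 and Spearman rho = −0.173. By comparison, 100 simulations of unchanged groups against the same control CMPs gave a mean r of 0.464 (0.431 to 0.513). Covariance was −0.0358 against a simulated 0.00661, a difference of −0.0424. With 2 different control arrays in each comparison the mean r over 6 splits was −0.409 (−0.464 to −0.358). Among called genes 48 were lower in the knockout and higher in GMPs, where independent lists would share 3.77. Conversely, 27 were higher in the knockout and lower in GMPs, where independent lists would share 1.5. Genes called in the same direction numbered 1 higher and 4 lower (independent lists, 3.25 and 1.74). Prg2 and Epx, Cebpe and, in the opposite sense, Angpt1 and Egr1 were among the named genes called in both comparisons.

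Next, L-GMPs of the knockout leukaemia were compared with control L-GMPs. The granulocyte-monocyte genes that fell in knockout CMPs lay near control levels here in the median: 0 of 14 receptors and regulators and 0 of 12 monocyte genes passed in limma's BH-adjusted test. The median changes were 0.27 for primary granule genes, 0.01 for monocyte genes and −0.15 for receptors and regulators (camera BH-adjusted p = 0.662, 0.986 and 0.743). The SEs here count 3 arrays of 1 leukaemia as replicates. Array weights were 1.31 and 1.26 for these and 0.31 and 0.85 for control L-GMPs. Passing both weightings therefore does not guard against likeness within 1 leukaemia. Genes that rose under equal and under array weights included the protocadherin Pcdh7 (5.59 ± 0.19), at 10.10 ± 0.08 (SD, n = 3) against 4.50 ± 0.30 (SD, n = 4). They also included the phosphodiesterase Pde3b (4.34 ± 0.72), Klhl4 (4.16 ± 0.13), Xlr (4.20 ± 0.57), Zc3h12c (4.14 ± 0.61), Ak4 (3.81 ± 0.50), the carbonic anhydrase Car2 (4.20 ± 0.47) and the stem cell regulator Mecom (4.29 ± 0.98). Cebpa fell by 2.71 and the mast cell carboxypeptidase Cpa3 (−4.74 ± 0.77) fell. So did Iftap (−3.30 ± 0.44), Gng11 (−2.79 ± 0.58), Trps1 (−2.20 ± 0.51), Slfn4 (−1.69 ± 0.19) and Rps4l (−1.55 ± 0.26).

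Of the fixed lists, the stem cell list had 2 of 13 higher in knockout L-GMPs, Mecom and Hoxb5 (2.30 ± 0.28) (2 adjusted over the list alone). The cytokine response list had Ccnd2 (1.07 ± 0.16) and Pim1 (1.63 ± 0.30) higher and Id1 (−0.99 ± 0.21) lower among 14 (4 higher and 2 lower adjusted over the list alone). Car2 was the 1 of 16 erythroid genes, Cpa3 the 1 of 13 mast cell genes, Nkg7 (2.59 ± 0.47) the 1 of 12 lymphocyte genes and the histone demethylase Jmjd1c (1.27 ± 0.16) the 1 of 15 MLL-fusion targets that changed (adjusted over the list alone, 1, 1, 1 and 2). Vcam1 (−1.44 ± 0.34), Prss57 (1.98 ± 0.44) and Ifit3 (−0.66 ± 0.16) passed with equal weights and not with array weights. Limma's BH-adjusted p with array weights was 0.0909, 0.0559 and 0.0594. Adjusted over the list alone, 2 secondary granule genes were lower, and 1 primary granule gene higher and 1 lower. The 18 lists gave 0 calls in camera (2 had an unadjusted p below 0.05), stromal genes lying closest (adjusted p = 0.0569). The 0 depended on the arrays: 6 of 7 single arrays left out in turn gave 1 or 2 lists, and high Xist as a covariate gave 2. The median and mean differed in sign for the stem cell (−0.10 and 0.41), erythroid, megakaryocyte, lymphocyte and cytokine lists.

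Counted over all genes, 651 differed between knockout and control L-GMPs (limma, BH-adjusted), 419 higher and 232 lower, 165 and 27 of them at least 2-fold. Array weights called 617, of which 473 were shared, and the arrays did not overlap for 2773 genes (13.9%, against 5.71% by chance). Because the 3 knockout arrays come from 1 leukaemia, averaging them to 1 sample left 90 genes. Similarly, a random block for the leukaemia left 374, and a fit on these 7 arrays alone left 11. Primary recipients alone, with 1 knockout array taken to vary like the other groups, gave 132. The count was 2449 without primary control L-GMP array 1, 415 without secondary control array 2. It was 427 and 409 without secondary knockout arrays 1 and 2. When secondary knockout L-GMP array 2 was dropped, the BH-adjusted p was 0.0787 for Mecom (4 of 7). After removal of secondary control L-GMP array 2 the BH-adjusted p was 0.0862 for Trps1 (3 of 7). Without secondary knockout L-GMP array 1, the BH-adjusted p was 0.0623 for Id1 (2 of 7).

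Whether the knockout effect differed between L-GMPs and CMPs was tested as a difference of the 2 effects. The effect was higher in L-GMPs for Elane (4.86 ± 0.69), Ctsg (4.13 ± 0.57), Prtn3 (3.62 ± 0.58), Prss57 (4.10 ± 0.59), Ms4a3 (4.58 ± 0.81), Ly86 (4.35 ± 0.53), F13a1 (4.34 ± 0.41), Csf1r (3.29 ± 0.33) and Irf8 (2.32 ± 0.41), genes of neutrophil granules, monocytes and their receptors. Of 9 primary granule genes 5 differed upward (7 up and 1 down adjusted over the list alone), of 12 monocyte genes 5 (10 adjusted over the list alone) and of 14 receptors and regulators 4 (5 adjusted over the list alone). The list medians were 3.62, 1.95 and 0.95. Camera's BH-adjusted p was 3.13e-07, 5.71e-11 and 1.33e-05 for these lists, and adjusted p = 0.0515, 0.0343 and 0.124 with an estimated correlation. The adenylate kinase Ak4 (5.35 ± 0.67), the heparanase Hpse (4.82 ± 0.29), Zc3h12c (4.17 ± 0.82), Hoxb5 (2.56 ± 0.37) and Car2 (3.47 ± 0.63) differed in the same direction. The lists of secondary granule, stem cell and lymphocyte genes had a median of other sign than their mean or test. Differences below 0 were found for Cpa3 (−5.95 ± 1.04), Tox (−3.76 ± 0.68), Gng11 (−3.46 ± 0.77), Iftap (−2.97 ± 0.59), Ctla2b (−2.86 ± 0.58), Fnbp1l (−2.55 ± 0.46), Ctla2a (−2.43 ± 0.39) and Phlda1 (−2.27 ± 0.35).

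**Figure D2:**
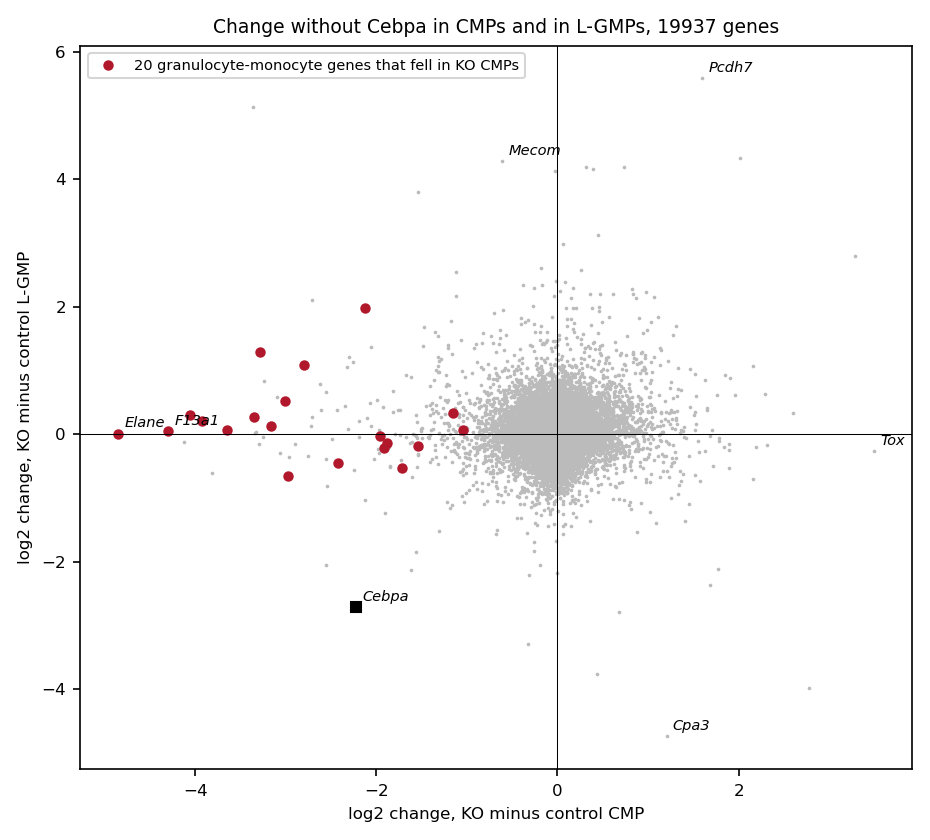
Log2 change without Cebpa in CMPs (horizontal axis) against that in L-GMPs (vertical axis), each point a gene, with the 20 granulocyte-monocyte genes that fell in knockout CMPs marked. Their median change was −2.89 in CMPs and 0.07 in L-GMPs.

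Immediate early genes differed downward, Egr1 (−2.14 ± 0.32) and Jun (−1.34 ± 0.33) of 11 (2 adjusted over the list alone; camera p = 0.000103, and adjusted p = 0.275 with an estimated correlation). Cell cycle genes had 0 of 24 past limma's threshold (Aurkb 0.75 ± 0.20, 2 adjusted over the list alone) and camera BH-adjusted p = 0.000351, with adjusted p = 0.455 with an estimated correlation. Stromal genes had 0 of 12 (Vcam1 −1.59 ± 0.45, 1 adjusted over the list alone) and camera p = 0.0127, with adjusted p = 0.233 with an estimated correlation. In all, 558 genes had a BH-adjusted difference of effects in limma, 402 upward and 156 downward, 547 of them also with array weights. Without primary control L-GMP array 1 the count was 1603. With the knockout leukaemia averaged to 1 sample it was 159, and Xist as a covariate gave 245. Array weights called 1280 and a fit on the 15 arrays alone 1582. Leaving out knockout CMP array 1 gave a BH-adjusted p of 0.0867 for Jun (9 of 15). With primary knockout L-GMP array 1 left out, the BH-adjusted p was 0.957 for the cell cycle list (1 of 15). When secondary control L-GMP array 2 was dropped, the BH-adjusted p was 0.0745 for the stromal list (2 of 15). Across all genes the knockout effects in CMPs and L-GMPs had r = 0.0337. They shared 48 genes called higher and 21 called lower (independent lists, 9.52 and 6.12). Called in opposite directions were 5 and 22 (independent lists, 5.27 and 11.1).

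Control L-GMPs were then set against the knockout MLL-AF9 progenitors that had caused no leukaemia. Leukaemia, Cebpa genotype and sort gate all differed between these sides and cannot be told apart here. Genes of neutrophil granules and monocytes were far higher in the leukaemic cells: Elane (6.46 ± 0.44), Ctsg (5.53 ± 0.37), Prtn3 (5.12 ± 0.37), Mgst1 (4.60 ± 0.50), Hp (6.89 ± 0.28), F13a1 (4.97 ± 0.26), Anxa3 (4.96 ± 0.29) and Ly86 (4.73 ± 0.34). Beside them stood the prostaglandin-degrading enzyme Hpgd (7.31 ± 0.13), at 11.63 ± 0.11 (SD, n = 4) against 4.30 ± 0.14 (SD, n = 5). Of 9 primary granule genes 6 were higher, of 12 monocyte genes 9 and of 14 receptors and regulators 11, among the latter Csf3r (1.92 ± 0.14), Csf1r (2.29 ± 0.21) and the myeloid factor PU.1, Spi1 (1.70 ± 0.19). With array weights 6, 7 and 10 passed, and 7 up, 9 up with 1 down, and 11 up with 1 down adjusted over the list alone. Lower were Ctla2a (−6.82 ± 0.25), granzyme B, Gzmb (−5.92 ± 0.86), the IgE receptor chain Fcer1a (−5.14 ± 1.04), the thrombin receptor F2r (−4.40 ± 0.34), Plxdc2 (−4.34 ± 0.41), Scin (−4.11 ± 0.67), Pf4 (−4.06 ± 0.60), Angpt1 (−3.97 ± 0.34), cyclin D2, Ccnd2 (−2.88 ± 0.14), and Car1 (−4.43 ± 0.65). Erythroid genes were lower for 12 of 16 (4 also with array weights, 14 adjusted over the list alone) and megakaryocyte genes for 5 of 12 (5 with array weights, 5 adjusted over the list alone). Mouse 9, whose KSLs and CMPs are 2 of the 5 reference arrays, stood apart in the mast cell list. The list median was 9.40 and 7.78 on its arrays and 4.43 to 4.98 on the other 3. Mouse 9 was also highest in Fcer1a (11.95 and 10.63), with mouse 4 (8.70) between it and mouse 11 (5.41 and 6.43). The same order held for Gzmb, at 12.35 and 12.12, 10.73, and 7.44 and 8.32. Without mouse 9, a choice made after its values were seen, 5096 genes differed, and Gzmb changed by −4.26 and Scin by −2.82.

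The medians of the primary granule, monocyte, and receptor lists in control L-GMPs against the progenitors were 3.89, 2.18 and 1.81. Camera's BH-adjusted p was 3.05e-08, 4.77e-09 and 6.21e-10 for these lists, and adjusted p = 0.0261, 0.0261 and 0.0261 with an estimated correlation. The other 9 called lists lost the call with an estimated correlation. Of these, secondary granule genes were higher for 9 of 15 (4 with array weights, among them Cebpe (2.26 ± 0.19) and Lcn2 (2.95 ± 0.41), 10 adjusted over the list alone; adjusted p = 0.0932 with an estimated correlation). The erythroid and megakaryocyte lists had adjusted p = 0.125 and 0.354 with an estimated correlation. In the cytokine response list 6 of 14 were lower and 2 higher, Id1 (1.73 ± 0.18) among the latter (4 and 2 with array weights, 9 and 2 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation). Immediate early genes were lower for 3 of 11, Egr1 (−1.62 ± 0.21) and Junb (−1.26 ± 0.18) under both weightings (4 adjusted over the list alone; adjusted p = 0.386 with an estimated correlation). The stem cell genes Angpt1 and Mllt3 (−1.38 ± 0.24) fell (2 of 13, 2 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation). Among 15 MLL-fusion targets Pbx3 (1.57 ± 0.37) rose and Bcl2 (−0.96 ± 0.19) fell under both weightings, of 4 and 1 with equal weights (5 and 1 adjusted over the list alone; adjusted p = 0.529 with an estimated correlation). Mouse 9 had low levels of this list as well (medians 6.44 and 5.49 against 8.28 to 8.63 on the other reference arrays). Without it the list median turned from 0.57 to −0.12 (camera BH-adjusted p = 0.69). Cell cycle genes were higher for 5 of 24, Aurka (0.65 ± 0.10) with both weightings (5 adjusted over the list alone; adjusted p = 0.537 with an estimated correlation). In addition, 2 of 16 ribosome biogenesis genes were lower with equal weights only (2 adjusted over the list alone; adjusted p = 0.529 with an estimated correlation).

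In total 3780 genes differed between control L-GMPs and the non-leukaemic progenitors (limma, BH-adjusted), 1696 higher and 2084 lower, 383 and 567 of them at least 2-fold. The arrays did not overlap for 1542 genes (7.73%, against 1.59% by chance). Noise was unequal here: in data simulated with each group's own noise 66.9% of the calls were false with equal weights and 4.79% with array weights, which called 1250 genes, all among the 3780. A fit on these 9 arrays alone called 493 genes, KSLs as the only reference 2282, and high Xist as a covariate 2278. After removal of MLL-AF9 KSL array 1 the BH-adjusted p was 0.712 for the cell cycle list (6 of 9), 0.0675 for the immediate early list (1 of 9) and 0.645 for the MLL-fusion target list (5 of 9). Without primary control L-GMP array 1, the BH-adjusted p was 0.114 for the stem cell list (6 of 9). Leaving out MLL-AF9 KSL array 2 gave a BH-adjusted p of 0.556 for the ribosome biogenesis list (4 of 9).

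Knockout L-GMPs were compared with the same progenitors, with little difference in Cebpa (0.02 ± 0.18, limma BH-adjusted p = 0.978). The sort gates still differed, and the knockout leukaemia had arisen after vectors expressing IL-3 and GM-CSF were injected. Leukaemia, gate and vectors cannot be told apart here, and the 3 arrays stand for 1 leukaemia. Primary granule genes were higher for 7 of 9 and lower for 1 (7 and 1 adjusted over the list alone), among them Elane (6.47 ± 0.50), at 11.39 ± 0.36 (SD, n = 3) against 4.91 ± 0.52 (SD, n = 5), Ctsg (5.74 ± 0.41), Prtn3 (5.39 ± 0.42) and Ms4a3 (5.18 ± 0.58). Monocyte genes were higher for 8 of 12 (8 adjusted over the list alone), including F13a1 (5.01 ± 0.29) and Ly86 (5.03 ± 0.38). So were receptors and regulators, 10 of 14 (9 also with array weights, 10 adjusted over the list alone), including Csf3r (1.99 ± 0.16) and Csf1r (2.41 ± 0.24). The largest rises also held Hpgd (6.81 ± 0.15), Hp (6.76 ± 0.32), Xlr (5.59 ± 0.56) and the ephrin receptor Epha7 (5.48 ± 0.45). The largest falls were Ctla2a (−7.36 ± 0.28), Gzmb (−6.10 ± 0.97), Car1 (−5.94 ± 0.74), Cpa3 (−5.47 ± 0.75), Fcer1a (−5.44 ± 1.17), F2r (−4.90 ± 0.39), the lymphoid enzyme Dntt (−4.61 ± 0.94) and Plxdc2 (−4.40 ± 0.47). Erythroid genes were lower for 11 of 16 (7 with array weights, 13 adjusted over the list alone), with Gata1 (−2.62 ± 0.30) and Gfi1b (−2.22 ± 0.31) among them. Mast cell genes were lower for 3 of 13 (3 adjusted over the list alone and 1 higher), beside the high mast cell list on both mouse 9 reference arrays. Without mouse 9, 3569 genes differed, and Gzmb changed by −4.44, Fcer1a by −3.30 and Cpa3 by −4.14.

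The primary granule, monocyte and receptor lists of knockout L-GMPs had medians of 4.47, 2.13 and 1.66. Camera's BH-adjusted p was 2.12e-09, 2.16e-09 and 2.12e-09 for these lists, and adjusted p = 0.0244, 0.0244 and 0.0244 with an estimated correlation. The other 8 called lists lost the call with an estimated correlation. They were secondary granule (4 of 15 higher, 4 adjusted over the list alone, Cebpe (2.71 ± 0.21) among them; adjusted p = 0.234 with an estimated correlation) and erythroid (adjusted p = 0.198 with an estimated correlation), then megakaryocyte (4 of 12 lower, 4 adjusted over the list alone, Pf4 (−4.22 ± 0.68) and Gp5 (−2.37 ± 0.36); adjusted p = 0.359 with an estimated correlation). Next came cytokine response (5 of 14 lower and 1 higher, 8 and 1 adjusted over the list alone, Ccnd2 (−1.81 ± 0.16) and Socs2 (−1.35 ± 0.34); adjusted p = 0.234 with an estimated correlation). Without mouse 9 Socs2 changed by −0.77 and Ccnd2 by −1.76. Immediate early genes were lower for 3 of 11 (4 adjusted over the list alone), Egr1 (−2.41 ± 0.23) and Jun (−1.33 ± 0.24) among them (adjusted p = 0.322 with an estimated correlation). The MLL-fusion targets Jmjd1c (1.17 ± 0.15) and Hoxa7 (0.90 ± 0.21) rose, of 3 higher and 1 lower, Bcl2 (−1.14 ± 0.21), among 15 (5 and 1 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation). Without mouse 9, whose levels of this list were low, its median was 0.45 in place of 1.03 (camera BH-adjusted p = 0.0282). Ribosome biogenesis genes were lower for 4 of 16 (2 with array weights, Polr1b (−0.80 ± 0.16) and Rrp9 (−0.54 ± 0.12), 5 adjusted over the list alone; adjusted p = 0.293 with an estimated correlation). Cell cycle genes were higher for 5 of 24 (4 with array weights, 6 adjusted over the list alone, Aurka (0.64 ± 0.11) and Bub1 (0.85 ± 0.15); median 0.11, adjusted p = 0.409 with an estimated correlation). Without the primary knockout L-GMP array the list median turned to −0.17. With primary knockout L-GMP array 1 left out, the BH-adjusted p was 0.345 for Aurka (1 of 8) and 0.216 for Bub1 (1 of 8). When MLL-AF9 KSL array 1 was dropped, the BH-adjusted p was 0.416 for the cell cycle list (4 of 8).

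For knockout L-GMPs 2632 genes differed from the progenitors (limma, BH-adjusted), 1450 higher and 1182 lower, 553 and 424 of them at least 2-fold. Of all, 1932 also passed with array weights. The arrays did not overlap for 2516 genes (12.6%, against 3.57% by chance). With the knockout leukaemia averaged to 1 sample 952 differed, and a fit on these 8 arrays alone called 347. Primary recipients alone, with 1 knockout array taken to vary like the other groups, gave 882. The comparisons of control L-GMPs, from 4 recipients, and of the knockout leukaemia shared 1750 genes called in the same direction against the progenitors and 21 in opposite directions. Independent lists would share 247 in the same direction. In 20 simulations of unchanged groups at most 0 were shared. Few genes pass the adjustment in unchanged groups, and every group was given the same noise, unlike the data. This 0 is therefore no baseline for the shared genes. With different mice as the reference of each, 1575 and 1595 were shared in the same direction (independent lists, 414 and 557). In opposite directions were then 61 and 96 genes in the first such split of the mice and 133 and 210 in the other. Across genes r was 0.792 against a simulated 0.402, and the covariance 0.245 against 0.0155, a difference of 0.229. The simulated values hold for equal noise, while the reference CMPs and KSLs had 1.33 and 1.48 times the mean noise. With different mice as references r was 0.551 and 0.442 and the covariance 0.203 and 0.174. Elane, Ctsg, Prtn3, Hp, F13a1, Ly86, Csf1r and Csf3r were higher and Ctla2a, Gzmb, Fcer1a, Car1, Pf4 and Ccnd2 lower in both.

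**Figure D3:**
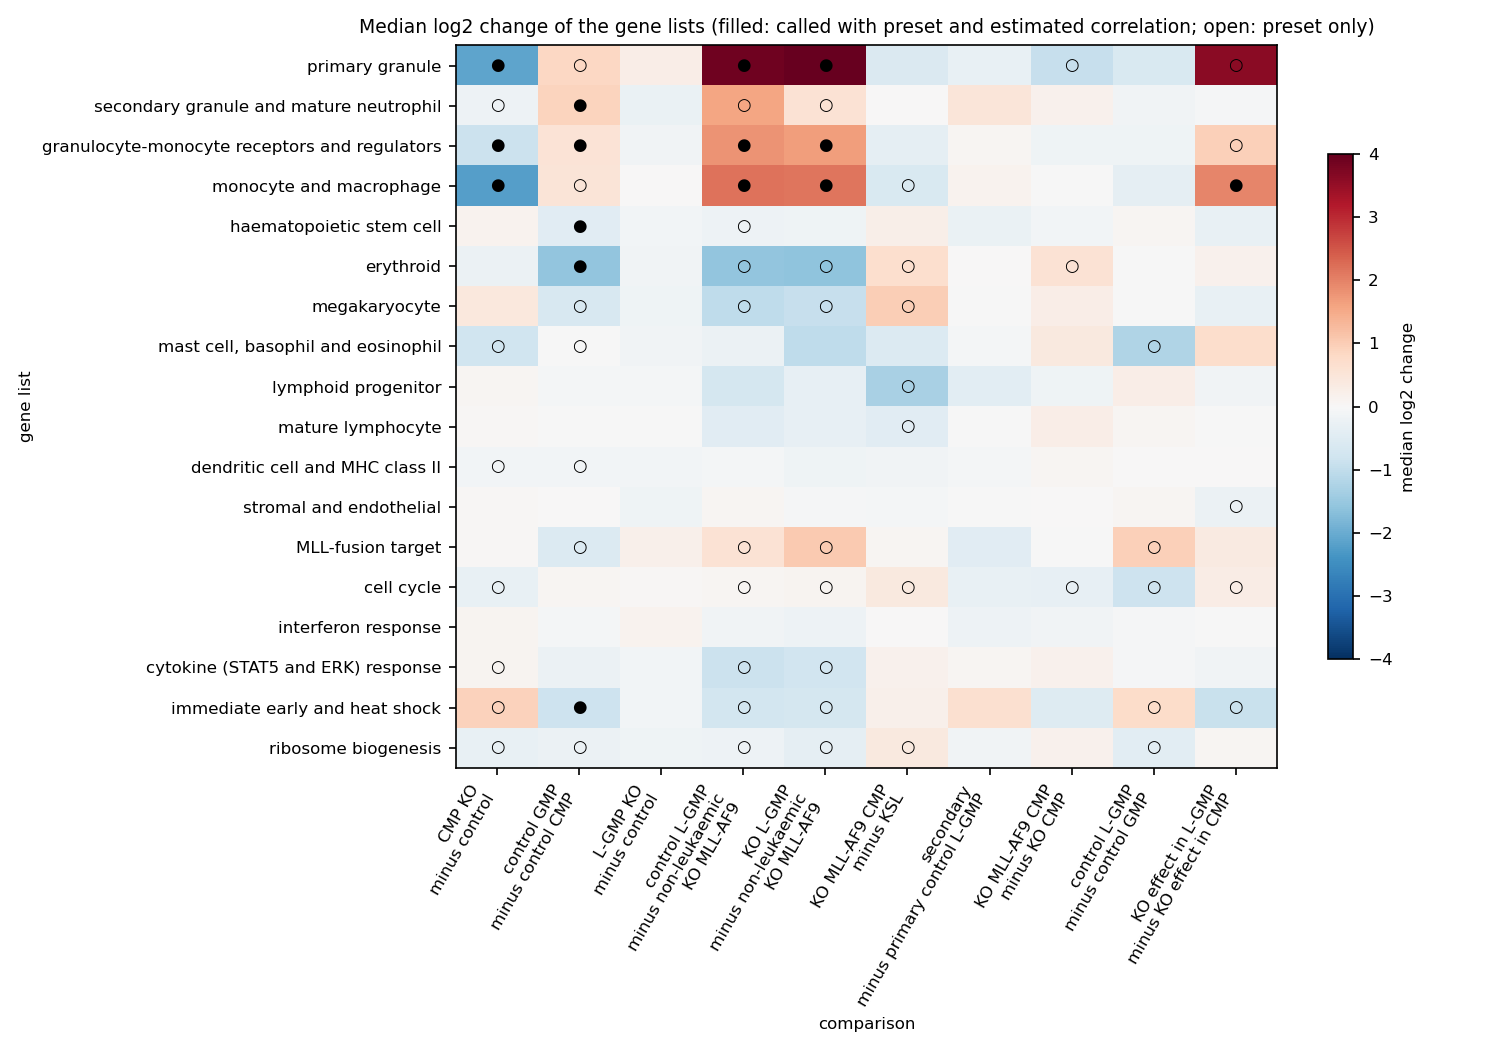
Median log2 change of each of the 18 gene lists (one per line of the grid) in the 10 contrasts (one per column), coloured from lower to higher, with filled marks where camera called the list under the preset and the estimated correlation and open marks where it did so under the preset alone. Primary granule, monocyte and receptor genes carry filled marks in knockout CMPs (lower) and in both comparisons of L-GMPs with non-leukaemic progenitors (higher).

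Within the non-leukaemic MLL-AF9 mice, CMPs were compared with KSLs. Log2 changes below 0 in CMPs were measured for the lymphoid genes Il7r, the IL-7 receptor (−3.74 ± 1.17), Ly6d (−2.03 ± 0.59) and Jchain, the immunoglobulin joining chain (−4.85 ± 0.83). Above 0 were the histone gene H4c3 (2.01 ± 0.42), the serine pathway enzyme Shmt2 (1.66 ± 0.26) and the cell cycle genes Birc5 (0.74 ± 0.14) and Aurkb (0.87 ± 0.17). None of these passed with array weights, so they stand as values. The 3 genes that passed under both weightings were lower in CMPs. They were the immunoglobulin segment Igkv19-93 (−3.31 ± 0.36 with array weights, BH-adjusted p = 0.000942), Cyp2c67 (−0.18) and Spink13 (−0.25), named after their values were seen. The changes of Cyp2c67 and Spink13 were identical under both weightings, although the CMP arrays had unequal weights. Their CMP arrays thus held 1 common value, which points to the floor, since values above it were almost never identical. These 2 small changes are therefore no sound calls. Mouse 9 stood apart from the other mice in a pair of gene groups. Median levels of the mast cell list were 9.40 in KSLs and 7.78 in CMPs of mouse 9 and 4.43 to 4.98 in mice 11 and 4. For the MLL-fusion target list they were 6.44 and 5.49 in mouse 9 and 8.28 to 8.63 in the others.

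**Figure D4:**
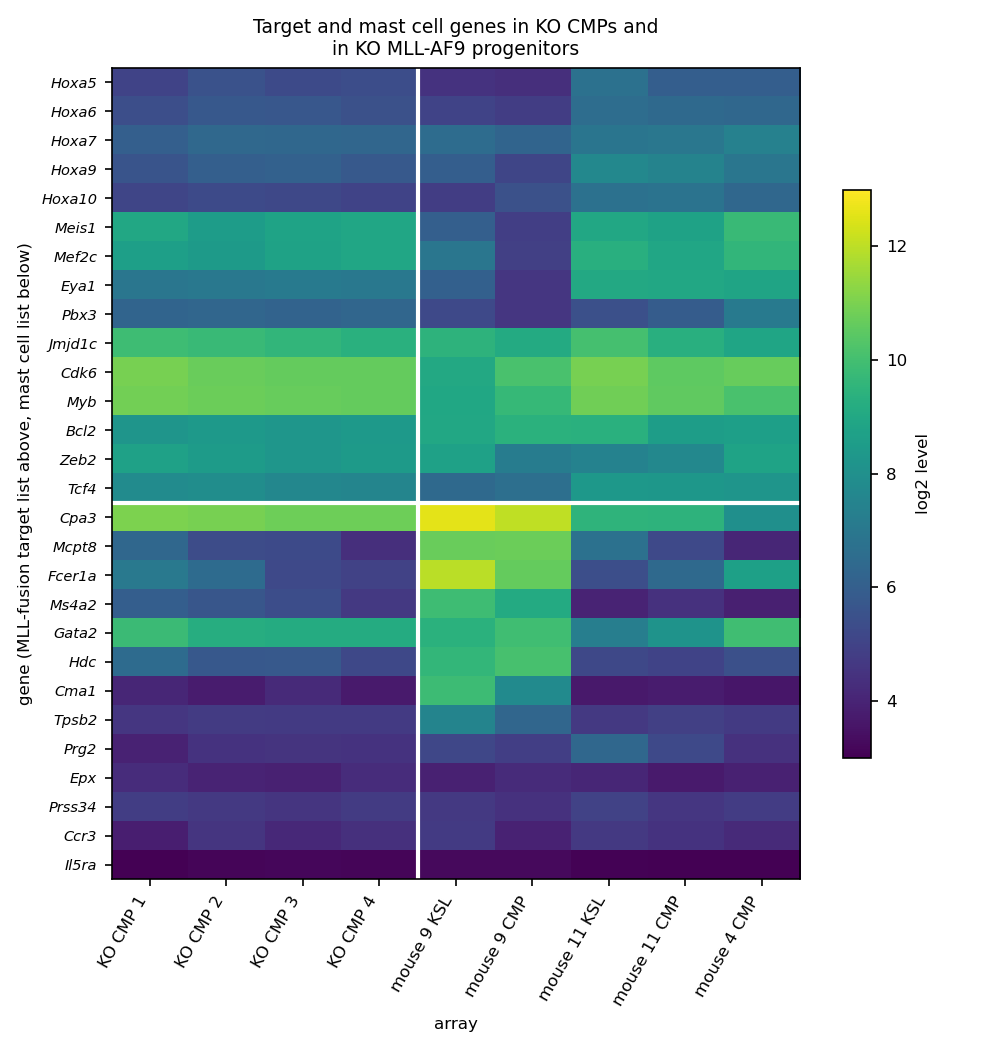
Log2 level (colour) of MLL-fusion target genes (upper part) and mast cell, basophil and eosinophil genes (lower part) on the 4 knockout CMP arrays and the 5 arrays of knockout MLL-AF9 KSLs and CMPs. The list medians of mouse 9 were 6.44 and 5.49 for target genes and 9.40 and 7.78 for mast cell genes.

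By equal weights 662 genes differed between MLL-AF9 CMPs and KSLs (limma, BH-adjusted), 402 higher and 260 lower in CMPs. With 200 genes changed in 1 data set simulated with each group's noise, equal weights made 817 false calls (80.5%). That number exceeds the 662 called here, so the share cannot be read as theirs. On the real arrays, array weights called 3. The 3 and 2 arrays did not overlap for 3860 genes (19.4%, against 20% by chance). A fit on these 5 arrays alone gave 0 genes in limma, against 4029 with an unadjusted p below 0.05 in the fit of all arrays. KSLs and CMPs shared mice 9 and 11 and mouse 4 gave CMPs alone, and the mouse as a random block gave 1064 genes. The count was 2850 without MLL-AF9 KSL array 2, 2194 without MLL-AF9 CMP array 2 and 355 without MLL-AF9 CMP array 3. Camera called 7 lists with the preset correlation and 0 with an estimated one. Lower were the lymphoid progenitor list (median −1.29, 0 of 13 past limma's threshold and 6 lower adjusted over the list alone; adjusted p = 0.46 with an estimated correlation), then lymphocyte (−0.45, 0 of 12, 6 lower and 1 higher adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). So were monocyte genes (−0.60, 0 of 12, 1 adjusted over the list alone; adjusted p = 0.544 with an estimated correlation). Higher were cell cycle (0.38, 5 of 24 past the threshold with equal weights, 8 adjusted over the list alone; adjusted p = 0.479 with an estimated correlation) and ribosome biogenesis (0.41, 2 of 16, 6 adjusted over the list alone; adjusted p = 0.479 with an estimated correlation). The same held for megakaryocyte (1.00, 0 of 12, 2 adjusted over the list alone; adjusted p = 0.613 with an estimated correlation) and erythroid genes (0.66, 0 of 16, 0 adjusted over the list alone; adjusted p = 0.719 with an estimated correlation). Each of these calls also ended without single arrays. After removal of MLL-AF9 KSL array 2 the BH-adjusted p was 0.247 for the lymphoid progenitor list (1 of 5) and 0.0917 for the lymphocyte list (1 of 5). Without MLL-AF9 KSL array 1, the BH-adjusted p was 0.338 for the monocyte list (2 of 5), 0.38 for the cell cycle list (1 of 5), 0.397 for the ribosome biogenesis list (1 of 5) and 0.806 for the erythroid list (2 of 5). Leaving out MLL-AF9 CMP array 3 gave a BH-adjusted p of 0.283 for the megakaryocyte list (2 of 5).

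Secondary were compared with primary control L-GMPs. Primary array 2 had high Xist (10.97) and the Y-linked Eif2s3y at the floor of 3. Both secondary arrays had low Xist (3.64 and 3.79) and Eif2s3y at 8.69 and 8.55. By sex, primary array 2 was not the leukaemia passaged to either, so passage, sex and leukaemia cannot be told apart here. Among genes that passed with both weightings was the apolipoprotein gene Apoc1 (4.01 ± 0.22), at 8.30 ± 0.04 (SD, n = 2) against 4.29 ± 0.09 (SD, n = 2). The cohesin subunit Stag3 (2.91 ± 0.21), Aspa (2.86 ± 0.64), Pgrmc1 (2.74 ± 0.43), Maip1 (2.64 ± 0.30) and the kinase Bmx (2.61 ± 0.25) rose, and the lectin-like receptor Clec2d (−2.89 ± 0.39) fell. Lcn2 (3.76 ± 0.60), Angpt1 (−2.92 ± 0.50) and Nop2 (−1.11 ± 0.20) passed with equal weights. Their BH-adjusted p from limma with array weights was 0.0673, 0.0673 and 0.0525. No list was called by camera. The lowest BH-adjusted p were 0.155 for immediate early genes (median 0.66) and 0.239 for cell cycle genes (median −0.28). The receptor, erythroid, dendritic cell and stromal lists had medians (0.09, 0.01, −0.07 and −0.01) of other sign than their mean or test. Equal weights called 1536 genes, 805 higher and 731 lower, and array weights 151. These had 53.5% and 4.69% false calls in data simulated with each group's noise. The 2 arrays of each side did not overlap for 8266 genes (41.5%, against 33.3% by chance). A fit on these 4 arrays alone gave 0 genes in limma, against 4406 with an unadjusted p below 0.05 in the fit of all arrays. The equal-weights count was 3074 and 687 without primary arrays 1 and 2 and 366 without secondary array 2. With high Xist as a covariate it was 937. Camera called 1 list without primary array 2 and 1 without secondary array 2. With secondary control L-GMP array 2 left out, the BH-adjusted p was 0.106 for Aspa (1 of 4).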

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

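The tests of cells with intact Cebpa, of the intervals with the leukaemia averaged to 1 sample, of the 3 explanations for mouse 9 and of the share of granulocyte-monocyte cells were chosen only after the result was seen. Among named genes, 7 of 128 sets of 4 arrays had 1 array far from the other 3 by Dixon's criterion, where chance marks about 1 in 20 groups. In knockout CMP array 1 these were Ctla2b at 9.27 (the others 8.88 to 8.93), Irf8 at 5.83 (the others 5.41 to 5.48) and Prg2 at 3.97 (the others 4.48 to 4.51). Knockout CMP array 4 had Sparc at 5.55 (the others 5.23 to 5.25). Control CMP array 3 had Csf1r at 8.11 (the others 8.31 to 8.33) and Jmjd1c at 8.61 (the others 8.86 to 8.91), and control CMP array 2 had Egr1 at 9.50 (the others 10.21 to 10.30).

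The knockout effect differed between L-GMPs and CMPs, in limma's test of the difference itself, for 22 of the 32 genes with the largest changes in either. As these genes were chosen for a change that enters the difference, a high share follows in part from the choice; over all genes it was 558 of 19937. The log2 difference lay above 0 for the granule and monocyte genes Elane (4.86), Ctsg (4.13), Prtn3 (3.62), F13a1 (4.34), Ly86 (4.35) and Ms4a6c (3.72), and for Hp (4.00) and Anxa3 (3.20). It also did so for Pcdh7 (3.99), Car2 (3.47), Xlr (3.89), Klhl4 (3.77), Zc3h12c (4.17) and Ak4 (5.35). Below 0 it lay for Tox (−3.76), Phlda1 (−2.27), Ctla2b (−2.86) and Lax1 (−2.06), which rose in knockout CMPs. The same sign was found for Cpa3 (−5.95), Iftap (−2.97), Gng11 (−3.46) and Slfn4 (−1.43), which fell in knockout L-GMPs.

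Probe sets with several symbols or none, 13120 in all, entered no count or list. Limma's BH-adjusted test called 229 for knockout CMPs, 20 for GMPs against CMPs, 240 for knockout L-GMPs, 1078 for control L-GMPs against progenitors, 573 for knockout L-GMPs against progenitors, 391 for MLL-AF9 CMPs against KSLs, 594 for secondary L-GMPs, 510 for MLL-AF9 against knockout CMPs, 3518 for control L-GMPs against GMPs and 134 for the difference of knockout effects among them; what they measure was not analysed here.

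The 20 granulocyte-monocyte genes that fell in knockout CMPs had a median change of 0.07 in knockout L-GMPs (Prss57 1.98, Irf8 −0.66). Cells with intact Cebpa could not carry this: the median of these genes was 99.6% of the control level or more on each array, where Cebpa was 18.4%, 15.4% and 10.4%. Noise between arrays hiding an equal fall is argued against for this 1 leukaemia. With array weights the interval of the difference of effects lay above 0 for 20 of 20 genes. These were chosen from 35 measured list members for a fall that enters the difference, so a high share follows in part from the choice. With the leukaemia averaged to 1 sample the intervals rest on an assumed spread and do not decide this. MLL-AF9 without leukaemia did not restore them, the highest share of the fall regained on a knockout MLL-AF9 CMP array being −9.22%, below the knockout CMPs themselves. Such cells stay open, as does variation between knockout leukaemias, of which 1 was measured. Also open is whether leukaemia, the injected IL-3 and GM-CSF vectors or the GMP gate may go with these levels.

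In mouse 9, MLL-fusion target genes were lower than in mice 11 and 4. A mix-up of a single array is not settled. Over genes outside the MLL-fusion target and mast cell lists, the deviations of its KSL and CMP arrays from their groups correlated at 0.436. That was above every pair of arrays of different groups not known to share a mouse (highest 0.302). With 2 KSL arrays, however, the deviation of mouse 9 mirrors that of mouse 11. A signal shared by the mouse 11 arrays alone could therefore raise this value. Few cells with an active fusion stays open: the CMP list median lay −2.06 log2 units from the lowest of the knockout CMP arrays without virus, but these are no baseline for 1 array whose mast cell list lay far above theirs. Mast cells or basophils among the GFP-positive KSL and CMP gates are consistent with the mast cell list, whose mean median was 3.83 higher in mouse 9, with 8 of 13 genes (such as Cpa3, Mcpt8 and Fcer1a) at least 1 unit higher. Mouse 9's sort purity was not measured here, and this hypothesis was found and tested on the same arrays.

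Granulocyte-monocyte genes were lower in knockout CMPs. A smaller share of such cells in the Lin−c-kit+ gate would raise the markers of other cells alike. Megakaryocyte and mast cell genes moved apart by 1.04 ± 0.21 (0.39 and −0.65, list medians taken on each array and then averaged). However, members of the mast cell list went both ways and some mark GMPs. Without that list the megakaryocyte and erythroid (−0.23) changes lay 0.62 ± 0.31 apart, so a smaller share stays open, as does loss of transcription per cell. Sex of the animals is argued against, since 20 of 20 genes kept their call with high Xist as a covariate (median −2.87).

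Other splits of the compared arrays into groups of the same sizes were run to see whether chance can be excluded. For knockout against control CMPs chance is argued against, as 1 of 35 splits, the real one, called 979 genes and the highest other 5. The same holds for GMPs against CMPs (1 of 35 splits, 209 genes, highest other 10) and MLL-AF9 against knockout CMPs (1 of 35 splits, 972, highest other 3). Chance is not excluded, since 35 splits allow no share below 1 in 35 and no adjustment for the number of comparisons was made. Mixed splits also widen the spread within a side, so their low counts add little beyond the rank. The splits treat arrays as independent, which the 3 knockout L-GMP arrays of 1 leukaemia are not, nor are the KSL and CMP arrays of mice 9 and 11, so chance cannot be excluded by them for the comparisons that hold these. For knockout against control L-GMPs the real split called 584 genes and the highest other, with primary control array 1 beside the knockout arrays, 583 (1 of 35 splits as large). The difference of knockout effects gave 480 and 160 (1 of 100 splits drawn), and knockout L-GMPs against progenitors 2763 and 2124 (1 of 56 splits). Control L-GMPs against progenitors had 2 of 100 splits drawn at the real count of 3102 or above, the other one setting mouse 9's KSLs with the L-GMPs (4024), which points to a structure of the samples. For control L-GMPs against GMPs (1 of 35 splits, 4387, highest other 3172) chance is argued against only if the secondary recipients count as independent. Their donors are not given in the sources used here. Each side of a split was fitted as 1 group.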

How the results depend on the processing

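Mouse 9 left out, high Xist as a covariate and the crossed pairing are tests chosen only after the result was seen. Under alternatives other than leaving out arrays, 4382 calls of named genes stayed, 689 were lost, 99 were gained and 1 turned, and 1319 values had no call in either fit. With single arrays left out 2698 stayed, 504 were lost, 56 were gained and 951 had no call in either. Of calls of lists, 214 stayed, 76 were lost, 16 were gained, 1 was gained in the other direction and 1 turned. With single arrays left out these were 472, 67, 37, 4 and 2. Of gene counts, 87 stayed within 1.5 times the reported value and 40 did not. Quantile normalization again, array medians subtracted, no variance trend, dim genes left out and the mean of probe sets moved no count of the comparisons of groups that far. Signal near the floor of 3 limits what can be seen of dim genes.

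Fits on the compared arrays alone gave 3220 for knockout CMPs, 643 for GMPs against CMPs, 11 for knockout L-GMPs, 493 for control L-GMPs against progenitors, 347 for knockout L-GMPs against progenitors, 0 for MLL-AF9 CMPs against KSLs, 0 for secondary L-GMPs, 443 for MLL-AF9 against knockout CMPs, 3258 for control L-GMPs against GMPs and 1582 for the difference of knockout effects; they have fewer residual degrees of freedom and their own noise. Array weights gave 3762 for knockout CMPs, 1257 for GMPs against CMPs, 1250 for control L-GMPs against progenitors, 3 for MLL-AF9 CMPs against KSLs, 151 for secondary L-GMPs and 335 for MLL-AF9 against knockout CMPs, and 1280 for the difference of effects, giving less weight to noisy groups. Requiring 2-fold as well left 278 for knockout CMPs, 129 for GMPs against CMPs, 192 for knockout L-GMPs, 950 for control L-GMPs against progenitors, 977 for knockout L-GMPs against progenitors, 135 for MLL-AF9 CMPs against KSLs, 483 for secondary L-GMPs, 145 for MLL-AF9 against knockout CMPs and 988 for control L-GMPs against GMPs. The knockout leukaemia averaged to 1 sample, with fewer samples, left 90 for knockout L-GMPs, 952 for knockout L-GMPs against progenitors and 159 for the difference of knockout effects. Primary recipients only gave 132 for knockout L-GMPs and 882 for knockout L-GMPs against progenitors, and Angpt1 in control L-GMPs against GMPs turned to 0.37. KSLs as the only reference gave 2282 for control L-GMPs. High Xist as a covariate gave 593 for knockout CMPs, 2278 for control L-GMPs against progenitors, 937 for secondary L-GMPs, 192 for MLL-AF9 against knockout CMPs and 245 for the difference of knockout effects, and 2 lists for knockout L-GMPs. Without mouse 9, 6 lists passed for MLL-AF9 against knockout CMPs and 3 for MLL-AF9 CMPs against KSLs, and the MLL-fusion target list in control L-GMPs against progenitors turned to −0.12. For the Xist, mouse 9 and recipient settings the cause was not tested.

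Lists called with an estimated correlation, which widens the test, numbered 3 for knockout CMPs, 5 for GMPs against CMPs, 3 for control L-GMPs against progenitors, 3 for knockout L-GMPs against progenitors, 0 for MLL-AF9 CMPs against KSLs and 0 for MLL-AF9 against knockout CMPs, 0 for control L-GMPs against GMPs and 1 for the difference of effects. The preset called 10 for knockout CMPs, 12 for GMPs against CMPs, 12 for control L-GMPs against progenitors, 11 for knockout L-GMPs against progenitors, 7 for MLL-AF9 CMPs against KSLs and 3 for MLL-AF9 against knockout CMPs, 5 for control L-GMPs against GMPs and 6 for the difference. Leaving out single arrays moved gene counts to 530 to 817 for knockout CMPs, 70 to 196 for GMPs against CMPs, 409 to 2449 for knockout L-GMPs, 355 to 2850 for MLL-AF9 CMPs against KSLs, 366 to 3074 for secondary L-GMPs, 490 to 2035 for MLL-AF9 against knockout CMPs, 2764 to 6494 for control L-GMPs against GMPs and 383 to 1603 for the difference of knockout effects. Numbers of lists moved to 0 to 2 for knockout L-GMPs, 4 to 10 for MLL-AF9 CMPs against KSLs, 0 to 1 for secondary L-GMPs and 0 to 6 for MLL-AF9 against knockout CMPs. The cell cycle median in knockout L-GMPs against progenitors ranged from −0.17 to 0.32, and the erythroid median in MLL-AF9 CMPs against KSLs from −0.0323 (without KSL array 1) to 1.42. Where these fits, primary recipients only or the averaged leukaemia left 1 sample in a group, that lone sample is assumed to vary like the other groups. The cause was not tested.

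The replicate block, with the pairing of MLL-AF9 KSLs and CMPs by mouse, gave 806 genes against 662, and a random block for mouse and leukaemia gave 374 for knockout L-GMPs and 1064 for MLL-AF9 CMPs against KSLs. The random block moved no other count it was run on by over 1.5 times, and it was not run for the difference of effects. Elsewhere the arrays share only a number. There the replicate block gave 688 for knockout CMPs, 145 for GMPs against CMPs, 483 for knockout L-GMPs, 1721 for secondary L-GMPs, 612 for MLL-AF9 against knockout CMPs and 2980 for control L-GMPs against GMPs, and not every array correlated best with its own number (knockout and control CMPs 0.0772, 0.0634, −0.00362 and −0.205). Secondary knockout and control L-GMPs of the same number correlated at −0.128, and the crossed replicate block gave 491 genes for knockout L-GMPs.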

Other observations

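Mouse 9 left out and high Xist as a covariate are tests chosen only after the result was seen. Knockout CMPs with MLL-AF9, taken from recipients without leukaemia, were compared with knockout CMPs that had not been transduced. Myeloperoxidase, Mpo (−3.97 ± 0.60), the G-CSF receptor Csf3r (−1.57 ± 0.16), Cd34 (−1.83 ± 0.18), Id3 (−2.04 ± 0.32), Apoe (−1.98 ± 0.37) and Sh2d1b1 (−2.59 ± 0.47) fell (log2 change ± SE, 3 and 4 arrays). The metal-binding protein Mt1 (1.70 ± 0.23), Myl10 (3.19 ± 0.64), Il18r1 (2.60 ± 0.56), Plxdc2 (2.35 ± 0.47), Thy1 (1.93 ± 0.50), Zmat3 (1.72 ± 0.37), Cyba (1.58 ± 0.28) and cyclin D2, Ccnd2 (0.81 ± 0.16), rose. Of 24 cell cycle genes 3 fell with both weightings, Bub1 (−0.98 ± 0.15), Top2a (−0.90 ± 0.18) and Mki67 (−1.20 ± 0.24) (4 adjusted over the list alone). That list had a median of −0.32 and camera BH-adjusted p = 2.08e-05, with adjusted p = 0.522 with an estimated correlation. Primary granule genes (3 of 9 lower with equal weights, 1 with array weights, 4 lower and 1 higher adjusted over the list alone) and erythroid genes (1 of 16 higher with equal weights) had camera BH-adjusted p = 0.0165 and 0.0228, and adjusted p = 0.522 and 0.913 with an estimated correlation. In all 972 genes differed by limma's BH-adjusted test, 302 higher and 670 lower, 309 also with array weights, and the arrays did not overlap for 3256 genes (16.3%, against 5.71% by chance). With each group's noise simulated, 34% of equal-weights calls were false and 10.1% with array weights. Without MLL-AF9 CMP array 3 the count was 2035 and without array 1 636, without knockout CMP arrays 1, 2, 3 and 4 505, 503, 490 and 614. It was 192 with high Xist as a covariate and 1205 without mouse 9, whose CMP array stood apart with a mast cell list median of 7.78 (4.43 and 4.89 in the other mice). Without it Mpo changed by −3.11, Plxdc2 by 1.57 and Zmat3 by 1.01. When MLL-AF9 CMP array 2 was dropped, the BH-adjusted p was 0.0591 for Il18r1 (1 of 7) and 0.411 for the erythroid list (4 of 7). After removal of MLL-AF9 CMP array 1 the BH-adjusted p was 0.14 for Thy1 (6 of 7). Without MLL-AF9 CMP array 3, the BH-adjusted p was 0.0554 for the cell cycle list (1 of 7) and 0.123 for the primary granule list (2 of 7).

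Control L-GMPs were compared with control GMPs, the normal cells of the same gate. MLL-fusion targets rose for 7 of 15 (7 adjusted over the list alone), among them the homeobox genes Hoxa9 (2.47 ± 0.45) and Hoxa7 (1.39 ± 0.21), Eya1 (3.98 ± 0.80) and Jmjd1c (0.93 ± 0.15). Other large rises were Hpgd (7.12 ± 0.15), Igf2bp3 (3.16 ± 0.27), Penk (2.93 ± 0.47), Olfm4 (2.62 ± 0.37) and Slfn4 (2.53 ± 0.18). Cell cycle genes were lower for 18 of 24 (17 also with array weights, 21 adjusted over the list alone), including Aurkb (−1.17 ± 0.14), Birc5 (−0.96 ± 0.12), Bub1 (−1.13 ± 0.15) and the replication factor Mcm3 (−0.85 ± 0.11). Met (−3.85 ± 0.20), Clec5a (−3.71 ± 0.35), Ak4 (−3.82 ± 0.48), Ifitm3 (−3.57 ± 0.46), the chemokine receptor Ccr2 (−3.28 ± 0.55), Csf1r (−1.55 ± 0.24), Irf8 (−1.42 ± 0.29), Ccnd2 (−1.70 ± 0.16) and Myc (−1.17 ± 0.24) fell. Of 13 mast cell, basophil and eosinophil genes 3 fell (3 adjusted over the list alone), Prss34 (−3.83 ± 0.46), Prg2 (−3.50 ± 0.44) and Epx (−2.60 ± 0.20). Camera called 5 lists and 0 with an estimated correlation. They were cell cycle (median −0.82; adjusted p = 0.387 with an estimated correlation), MLL-fusion target (0.94), ribosome biogenesis (−0.42, 5 of 16 lower with equal weights, 9 adjusted over the list alone), immediate early (0.74, 2 of 11 higher with equal weights, 3 adjusted over the list alone) and mast cell genes (−1.20). The last 4 had adjusted p = 0.661 with an estimated correlation. By limma 5052 genes differed (BH-adjusted), 2115 higher and 2937 lower, 4426 also with array weights, and the arrays did not overlap for 6141 genes (30.8%, against 5.71% by chance). Without control GMP arrays 2 and 3 there were 2764 and 3073. Leaving out secondary control L-GMP array 2 gave a BH-adjusted p of 0.0664 for the mast cell list (5 of 7). The L-GMPs had been transduced and transplanted, so leukaemia was not the only difference between these groups.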
